A study of Mus musculus with 6 samples.

How the data were processed

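RNA was measured in 6 libraries of mouse primary chondrocytes, cells that build cartilage, which were cultured without being made to differentiate. In 3 libraries both Nf2 alleles were floxed and no Cre was present (control 1 to 3), and in 3 libraries Prx1-Cre, a recombinase active in limb bud mesenchyme, was carried with the floxed alleles (cKO 1 to 3). Per the labels' protocols, RNA was extracted with Trizol, 1.5 µg of total RNA was used, RNA was fragmented with magnesium and reverse transcribed, and dUTP was incorporated, a step used to keep strand information. The submitters' processing notes name genome build mm10. The aligner, the program that estimated transcript levels and the test behind the authors' comparison are not given in the sources used here. The groups and replicate numbers were taken from the sample titles.

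The deposited table holds FPKM values, which per the file headers are fragments scaled by transcript length and by each library's total, computed by the authors for each of 85882 Ensembl transcripts and each library. It lists no transcript at 0 in every library, which was checked on the table. The deposited fold is the ratio of mean FPKM in cKO to mean FPKM in control, which recomputation gave within 1% for 71165 of the 71165 transcripts with both means above 0, and the deposited log2 value is the log2 of that ratio. The authors' p-value and q-value come from a test that no header names, and transcripts marked significant in the table have a q-value under 0.05 and a change of at least 2-fold, with 0 exceptions. FPKM are not counts, so no main test was one that needs counts. Limma voom on implied fragment numbers was run only as an alternative. The low values were searched for the step that 1 fragment would make in transcripts of at least 800 bases. The step implied 16900000, 17400000 and 17700000 fragments in control 1 to 3, and 18100000, 18600000 and 19400000 in cKO 1 to 3. Between 16.0 and 19.7% of the low values lay within 2% of a step of a whole multiple, so whole reads were not recovered and the depths are estimates without an interval. Of the 85882 transcripts, 85239 are in the GENCODE M21 annotation of the same build, and 85004 of those (99.7%) have the same chromosome, start and end. Coordinates are 1-based on mm10.

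FPKM were summed over the transcripts of each of 29510 gene symbols, of which 46 are shared by more than 1 identifier. The 14080 genes with a mean of at least 0.5 FPKM over the 6 libraries were tested on log2(FPKM + 0.5), which understates the change of low genes. The test was limma 3.58.1 (R 4.3.3) with a mean-variance trend, 2-sided, without covariates, and Benjamini-Hochberg adjustment at 0.05. Every adjusted p of a gene or transcript given here comes from that test unless the authors' table is named. Single transcripts were tested in the same way. Fold changes are cKO over control. Errors are the standard deviation (SD) over 3 libraries for FPKM and the standard error (SE) of the fit for log2 changes. Tables were handled with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and plots were drawn with Matplotlib 3.10.9.

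Before the data were examined, 30 gene lists were fixed, together with the tests, most alternatives and the rule for naming genes. The lists cover Hedgehog target genes, Hedgehog pathway components, primary cilium genes, YAP/TAZ target genes, Hippo pathway components, merlin partners and ERM proteins, chondrocyte matrix and fate genes, hypertrophic chondrocyte genes, osteoblast genes, limb patterning genes, Wnt target genes, and BMP and TGF-beta target genes. They also cover cell cycle genes of S and G2/M phase, immediate early genes, the unfolded protein response, hypoxia and glycolysis, interferon response genes, and inflammatory and matrix-degrading genes. Markers of macrophages, osteoclasts, endothelium, skeletal muscle, epidermis, glia and neurons, erythroid cells, fibroblasts, smooth muscle and adipocytes, sex-linked genes and mitochondrially encoded genes complete them. The 26 lists with at least 5 tested members were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, 2-sided, and Benjamini-Hochberg adjustment over lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance 1 way, stand beside it. GO and KEGG terms in the table with 10 to 500 tested genes were tested among higher and lower genes apart by a 1-sided Fisher exact test, against tested genes with an annotation. The GO cell reads as removed for 8680 transcripts of 1882 genes, so those genes are missing from terms.

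The named genes were 25 chosen in advance for the Hedgehog, cilium, Hippo, cartilage and limb questions, the 8 largest rises and 8 largest falls among genes past the test, and up to 4 members with the smallest p from each list. The largest changes needed separate groups, a mean of at least 1 FPKM in a group and an established symbol. Genes named outside that rule are said to be chosen after their values were seen. The tests were checked on simulated values for the gene comparison of 3 against 3 over 14080 genes with 200 changed. The recovered share was 61.2% at 1.5-fold, 91.0% at 2-fold and 98.5% at 4-fold, and 12 unchanged genes were called, 6.70% of the calls. The changed genes were drawn from those with a mean log2(FPKM + 0.5) of at least 1, so these shares do not cover lower genes. In a simulated shift of the limb patterning list by -0.50 on the log2 scale, that list was called and 0 of the others were. Simulated values were drawn independently for each gene. The list check therefore does not cover genes that vary together, on which the p-values of lists depend.

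Alternatives were pseudocounts of 0.1 and 1, no filter and a filter at a mean of 2 FPKM, median-of-ratios scaling, quantile normalization, limma without trend or with robust fitting, the replicate number as a block, protein-coding transcripts, the highest transcript per gene, a 2-fold threshold, the authors' own call, and leaving out each library in turn. Chosen after seeing the data were the Xist level as a covariate, transcripts of at least 200 bases, limma voom on the implied fragment numbers, and a count without large-intestine genes. No value column of other samples was present or used.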

Results

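The comparison addresses what loss of Nf2 in limb-derived cells changes, with limb and thumb development, primary cilia and Hedgehog signalling as the interests named in the series title. Nf2 encodes merlin, a tumour suppressor that links the membrane to the actin cytoskeleton and acts upstream of the Hippo kinases. RNA sequencing covered 3 control and 3 cKO libraries of primary chondrocytes, with an implied 16900000 to 17700000 fragments per control library and 18100000 to 19400000 per cKO library. Between 12441 and 12697 genes reached 1 FPKM per library. Correlations across genes, which are not independent replicates, were 0.987 to 0.989 within groups and 0.972 to 0.982 between them. The first principal component held 51% of the variance and separated the groups. Nothing in the labels says that replicates came from separate animals or cultures, so p-values measure the spread between these samples, which may be partly technical. Libraries of a group did differ in sex-linked transcripts. Xist was at 51.1, 0.525 and 53.9 FPKM in control 1 to 3 and at 51.4, 41.6 and 0.029 FPKM in cKO 1 to 3. These values argue against all 3 libraries of a group being repeats of 1 RNA sample. They do not show that each came from a separate animal.

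Nf2 itself (ENSMUSG00000009073, chromosome 11, 4765845 to 4849536) was present at 16.7, 16.6 and 14.1 FPKM in control 1 to 3 and at 17.5, 15.6 and 18.1 FPKM in cKO 1 to 3. The log2 change summed over its 12 transcripts was 0.11 (SE 0.091, limma adjusted p = 0.463). Over 19 alternatives it lay between -0.21 and 0.17 (limma adjusted p 0.127 to 0.833), so its sign depends on the setting. The table gives no value per exon, so a sum over transcripts, which also takes reads outside a deleted part, does not check the deletion. The main transcript ENSMUST00000109910 (16 exons) stood at 14.1 ± 1.12 FPKM in control and 9.52 ± 2.14 FPKM in cKO (SD, n = 3), or 89.0% and 55.7% of the gene's signal. ENSMUST00000056290 (17 exons) stood at 0.742 ± 0.131 and 6.09 ± 2.87 FPKM, or 4.69% and 35.6%. Their log2 changes of -0.56 and 2.33 did not pass limma (adjusted p = 0.245 and 0.0543). The authors' deposited table gives ENSMUST00000056290 a fold of 8.21 with q = 1.62e-11. Both share 14 exons with the same start and end, and ENSMUST00000056290 has an additional exon of 45 bases (4780578 to 4780622) and a shorter last exon.

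**Figure D1:**
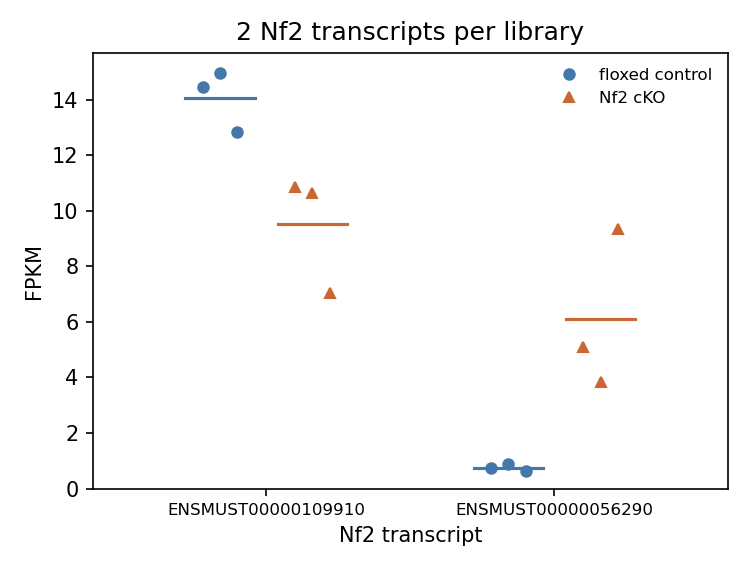
FPKM (linear axis) of the 2 most abundant Nf2 transcripts in each library, with circles for 3 controls, triangles for 3 cKO and lines at group means. ENSMUST00000109910 averages 14.1 in control and 9.52 in cKO, and ENSMUST00000056290 averages 0.742 and 6.09.

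Cartilage genes were lower in cKO than in control. Col2a1, the main cartilage collagen, fell from 3758 ± 405 to 1914 ± 210 FPKM (SD, n = 3), Acan, the large cartilage proteoglycan, from 172 ± 21.7 to 68.8 ± 4.40 FPKM, and Sox9, the master regulator of chondrocyte fate, from 27.0 ± 0.797 to 17.0 ± 0.529 FPKM. Gli1, a transcriptional target and effector of Hedgehog signalling, fell from 2.09 ± 0.304 to 0.493 ± 0.365 FPKM, and Ihh, the Hedgehog ligand of the growth plate, from 1.32 ± 0.384 to 0.206 ± 0.135 FPKM. Of 14080 genes, 1713 passed limma, 1070 higher (62.5%) and 643 lower, and 242 of them changed at least 2-fold, 60 higher and 182 lower. In 35.1% of genes the groups did not overlap, where chance gives 10%. With median-of-ratios scaling the split was 690 higher and 735 lower (48.4% higher) and with quantile normalization 666 and 735 (47.5%). Without control 1, 678 genes passed and without control 2, 537 passed.

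Of 34 chondrocyte matrix and fate genes, all tested, 28 fell, 0 rose and 6 did not pass, and 30 were lower when adjusted over the list alone. Cytl1, a cytokine-like protein of cartilage, fell from 353 ± 14.3 to 42.0 ± 3.27 FPKM (log2 change -3.06, SE 0.072, limma adjusted p = 7.1e-07). Comp, a matrix protein of cartilage, fell from 230 ± 18.2 to 73.0 ± 3.46 FPKM and Col27a1, a fibrillar collagen, from 45.2 ± 4.28 to 7.70 ± 1.53 FPKM. The log2 change was -0.97 for Col2a1 (SE 0.12, limma adjusted p = 0.00266), -1.31 for Acan (SE 0.098, adjusted p = 0.000257) and -0.65 for Sox9 (SE 0.061, adjusted p = 0.000768), with separate groups for each. The list median was -1.28 (camera adjusted p = 8.72e-31 with the preset correlation). The call was lost at adjusted p = 0.277 with an estimated correlation, and fry gave 0.00211. Without a filter on low values Col2a1 did not pass (adjusted p = 0.0631).

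Markers of other mesenchymal cells moved in both directions beside the cartilage genes. Of 18 tested fibroblast, perichondrium and tendon markers, 5 fell, 0 rose and 13 did not pass (8 lower when adjusted over the list alone), with a median of -0.54 (camera adjusted p = 7.99e-05). That list had adjusted p = 0.579 with an estimated correlation and 0.0988 by fry, and its median was -0.30 without a filter. Dcn, the small proteoglycan decorin, fell from 117 ± 20.4 to 43.0 ± 6.84 FPKM and Lum, the related lumican, from 110 ± 15.4 to 41.3 ± 14.0 FPKM, the latter not passing without a filter (limma adjusted p = 0.0618). Of 5 tested adipocyte markers, 3 rose, 0 fell and 2 did not pass, with the same 3 when adjusted over the list alone and a median of 0.46 (camera adjusted p = 0.0491). Its values were adjusted p = 0.579 with an estimated correlation and 0.0453 by fry, and without a filter the median was -0.02 (adjusted p = 0.734). Pparg, the adipocyte regulator, rose from 9.46 ± 0.612 to 21.7 ± 4.96 FPKM, Lpl, a lipase, from 8.07 ± 0.834 to 17.8 ± 4.01 FPKM, and Plin4, a lipid droplet protein, from 8.59 ± 0.493 to 12.0 ± 0.822 FPKM, the last not passing without control 2 (limma adjusted p = 0.0560). The adipocyte list did not pass without control 1, 2 or 3 (adjusted p = 0.0607, 0.0630 and 0.0671) or cKO 3 (0.150), nor with a pseudocount of 0.1 (0.0566), a mean of 2 FPKM or more (0.0687), protein-coding transcripts (0.0617) or the Xist covariate (0.0694).

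Of 20 hypertrophic chondrocyte genes 4 fell, 0 rose and 16 did not pass, the same 4 falling when adjusted over the list alone, with a median of -0.05 (camera adjusted p = 0.0775). The 4 were Smpd3, a sphingomyelinase (6.67 ± 1.10 to 1.94 ± 0.692 FPKM), Ihh, Cd200 and Bmp6. The list had adjusted p = 0.771 with an estimated correlation and 0.396 by fry, and camera gave 0.0384 without cKO 1 and 0.0151 without cKO 3. Its median was 0.0021 without cKO 2 and 6e-04 at a mean of 2 FPKM or more. Cd200 did not pass without control 1, control 3 or cKO 3 (limma adjusted p 0.0528 to 0.0756), nor Bmp6 without control 1, 2 or 3 or cKO 1 or 3 (0.0643 to 0.106). Col10a1, the collagen of hypertrophic cartilage, was at 50.5 ± 6.90 and 58.7 ± 3.85 FPKM (log2 change 0.22, limma adjusted p = 0.198). Of 14 osteoblast genes 1 rose and 13 did not pass, also when adjusted over the list alone (median 0.13, camera adjusted p = 0.716, 0.0143 without cKO 2, 0.875 with an estimated correlation and 0.644 by fry). That median was 0.28 without cKO 2, -0.02 without cKO 3 and -0.03 without a filter. The riser was Tnfrsf11b, the decoy receptor osteoprotegerin, from 136 ± 11.9 to 216 ± 28.5 FPKM, not passing without a filter on low values (limma adjusted p = 0.0543). Ibsp, bone sialoprotein, was at 40.9 ± 9.97 and 141 ± 85.4 FPKM (limma adjusted p = 0.0870, but 0.000730 without cKO 2).

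Of 12 tested Hedgehog target genes, 3 fell, 0 rose and 9 did not pass. Adjusted over the list alone, 7 were lower and 1 higher. Gli1 (chromosome 10, 127329882 to 127341974) fell by 1.44 on the log2 scale (SE 0.25, limma adjusted p = 0.0115), and the fall did not pass without a filter on low values (0.0657). The co-receptor genes Cdon and Gas1, which Hedgehog signalling is known to repress rather than activate, fell from 18.5 ± 1.86 to 11.4 ± 1.24 FPKM and from 50.1 ± 2.64 to 38.4 ± 4.01 FPKM. Ptch1, the Hedgehog receptor and target, was at 16.5 ± 1.22 and 11.6 ± 2.43 FPKM (log2 change -0.51, SE 0.14, limma adjusted p = 0.0540, 0.0397 without cKO 1). Ptch1 passed in 6 of 19 alternatives, among them median-of-ratios scaling (limma adjusted p = 0.0489) and quantile normalization (0.0493), and its highest adjusted p was 0.173. Hhip, another target, lay under the filter at 0.292 ± 0.071 and 0.074 ± 0.030 FPKM, and the authors' deposited table gives its transcript ENSMUST00000079038 q = 0.000575. The list, which holds both kinds of target, had a median of -0.32 (camera adjusted p = 0.00881), with adjusted p = 0.579 with an estimated correlation and 0.0526 by fry, and its median was -0.21 without a filter. Gas1 did not pass without control 1, 2 or 3 or cKO 2 or 3 (limma adjusted p 0.0501 to 0.0782).

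Hedgehog pathway components and cilium genes showed no shared direction. Of 29 components, 2 rose, 1 fell and 26 did not pass, with the same counts when adjusted over the list alone. Ihh fell by 1.36 on the log2 scale (SE 0.22, limma adjusted p = 0.00917), while Disp1, which releases the ligand, and Arrb1, an arrestin, rose by 0.34 and 0.53. Gli2, Gli3, Smo and Sufu had log2 changes of -0.28, -0.03, -0.07 and 0.17 and did not pass (adjusted p = 0.340, 0.838, 0.589 and 0.308). The component list had a median of 0.04 against a downward camera test (adjusted p = 0.973), and the median was -0.01 with median-of-ratios scaling. Of 87 primary cilium genes 5 rose, 2 fell and 80 did not pass (4 higher and 2 lower when adjusted over the list alone). Their median was 0.01, again with camera pointing down (adjusted p = 0.564), and it was -0.04 with median-of-ratios scaling. Aurka, a mitotic kinase that also drives cilium disassembly, rose from 27.6 ± 0.936 to 41.0 ± 1.80 FPKM and Plk1, another mitotic kinase, from 38.2 ± 1.98 to 48.2 ± 0.847 FPKM. Of the other cilium genes past the test, Sclt1 fell by 0.48 and Kifap3 rose by 0.28 on the log2 scale (limma adjusted p = 0.0188 and 0.0278). Sclt1 did not pass without control 1, 2 or 3 (limma adjusted p 0.05265 to 0.0734). Kifap3 did not pass in 8 of 19 alternatives, among them leaving out control 1, 2 or 3 or cKO 1 (0.0726 to 0.1001). Ift88, a component of intraflagellar transport, was at 6.47 ± 0.270 and 5.23 ± 0.048 FPKM (limma adjusted p = 0.0523). Ift88 passed in 5 of 19 alternatives, among them median-of-ratios scaling (limma adjusted p = 0.0354) and quantile normalization (0.0436), and its highest adjusted p was 0.174. Arl13b, a ciliary GTPase, had a log2 change of 0.08 (limma adjusted p = 0.560). Disp1 did not pass without control 1 or 2 or cKO 1 or 2 (limma adjusted p 0.0558 to 0.0951), Arrb1 without any control or cKO 1 or 2 (0.0522 to 0.145), and Plk1 without control 2 (0.0637).

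More targets of YAP and TAZ, the coactivators held back by Hippo signalling, rose than fell. Of 31 tested, 9 rose, 1 fell and 21 did not pass (11 higher and 2 lower when adjusted over the list alone), with a median of 0.24 (camera adjusted p = 0.0491). The list had adjusted p = 0.771 with an estimated correlation and 0.0821 by fry. Ankrd1 rose from 2.95 ± 0.744 to 7.84 ± 2.52 FPKM (log2 change 1.25, SE 0.23, limma adjusted p = 0.0127), Ccn1 from 191 ± 18.3 to 278 ± 46.7 FPKM (adjusted p = 0.0337), and Asap1, an Arf GTPase-activating protein, from 18.2 ± 0.405 to 28.5 ± 2.35 FPKM. Ccn2, a secreted matricellular protein like Ccn1, fell from 362 ± 17.4 to 252 ± 23.5 FPKM (log2 change -0.53, SE 0.083, adjusted p = 0.00747). Yap1 had a log2 change of 0.07 (adjusted p = 0.518). Ankrd1 did not pass without control 2 (adjusted p = 0.0578) or without a filter (0.0713). Ccn1 failed in 11 of 19 alternatives, among them leaving out control 1, 2 or 3 or cKO 2 or 3 (0.0585 to 0.119), and the list failed in 9 of 21, among them leaving out control 2 (0.109), control 3 (0.0983) or cKO 2 (0.0918), a pseudocount of 0.1 (0.0566), quantile normalization (0.0771) and protein-coding transcripts (0.0619).

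Of 38 Hippo pathway components 4 rose, 1 fell and 33 did not pass (5 higher and 1 lower when adjusted over the list alone; median 0.06, camera adjusted p = 0.553, median -0.02 with quantile normalization). Amotl2 and Amot, angiomotin proteins that bind YAP, were among the risers, from 79.7 ± 5.12 to 114 ± 19.7 FPKM and from 18.0 ± 2.11 to 26.2 ± 2.11 FPKM, and Stk38l, a kinase related to the Hippo kinases, fell from 14.98 ± 0.544 to 9.42 ± 0.857 FPKM. Of 22 merlin partners and ERM proteins 4 rose, 0 fell and 18 did not pass (5 higher when adjusted over the list alone), with a median of 0.21 (0.14 with quantile normalization; camera adjusted p = 0.00736). That list had adjusted p = 0.579 with an estimated correlation and 0.0305 by fry. Ezr, the membrane-actin linker ezrin, rose from 40.1 ± 2.33 to 64.1 ± 7.28 FPKM. The other risers were Amot, Slc9a3r1 and Rac1. Amotl2 did not pass without control 1, 2 or 3 or cKO 3 (limma adjusted p 0.0599 to 0.107), Amot without control 2 (0.0610) or a filter (0.0578), Slc9a3r1 without control 1 or 2 or cKO 1 or 2 (0.0552 to 0.1002), and Rac1 without any 1 of the 6 libraries (0.0558 to 0.173).

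**Figure D2:**
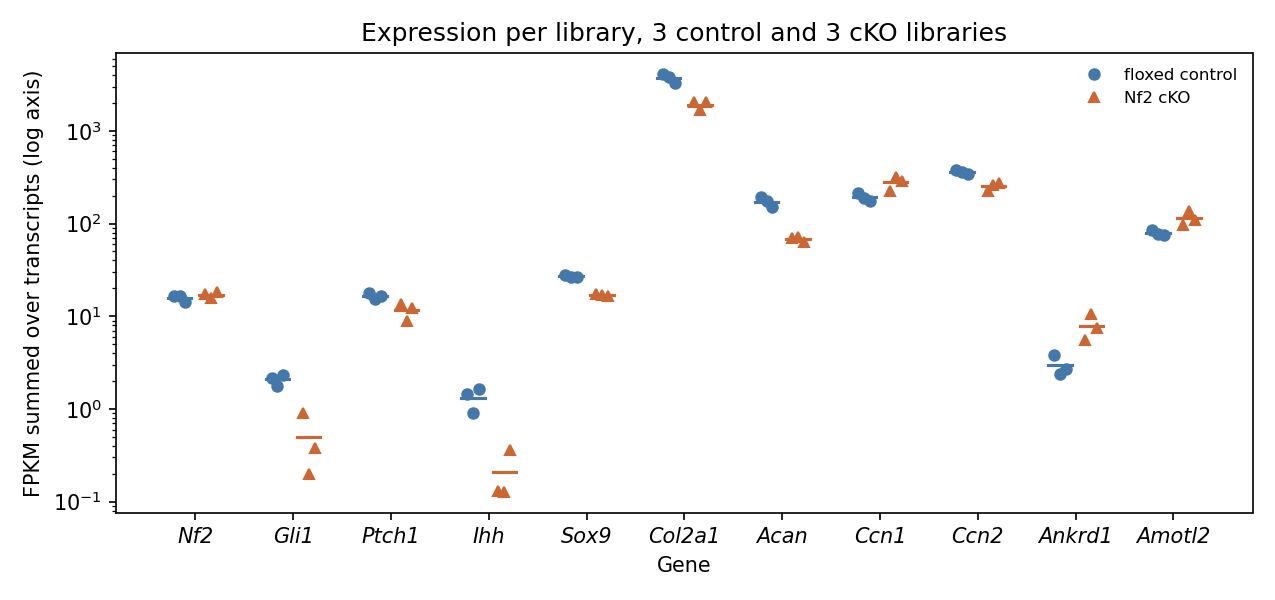
FPKM summed over transcripts (log axis) of 11 genes in each library, with circles for 3 controls, triangles for 3 cKO and lines at group means. Gli1, Ptch1, Ihh, Sox9, Col2a1, Acan and Ccn2 are lower in every cKO library than in any control, although Ptch1 did not pass limma (adjusted p = 0.0540). Ankrd1, Ccn1 and Amotl2 are higher in every cKO library, and the Nf2 groups overlap.

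Limb patterning genes changed singly. Of 46 tested, 5 rose, 5 fell and 36 did not pass, also when adjusted over the list alone. The median was -0.02 and the mean 0.003, with camera pointing down (adjusted p = 0.576). Bmp4, a bone morphogenetic protein, rose from 23.4 ± 2.00 to 48.9 ± 2.32 FPKM (log2 change 1.05, SE 0.078, limma adjusted p = 0.000257) and Prrx2, a limb mesenchyme homeobox gene, from 25.9 ± 0.960 to 41.5 ± 4.03 FPKM. Barx1, a homeobox gene of joint regions, fell from 19.9 ± 2.06 to 7.71 ± 2.07 FPKM and Grem1, a BMP antagonist, from 77.9 ± 12.6 to 43.3 ± 2.27 FPKM. Hand2, a regulator of the posterior limb bud, rose from 0.847 ± 0.130 to 1.49 ± 0.201 FPKM (adjusted p = 0.0478), a call lost without any 1 of the 6 libraries (0.0584 to 0.150). Prrx1, whose enhancer drives the Cre, was at 61.7 ± 6.14 and 47.7 ± 16.9 FPKM (adjusted p = 0.262). Hoxd13, Hoxa13 and Alx4, which pattern the digits, lay under the filter at means of 0.325, 0.236 and 0.111 FPKM in control and 0.604, 0.133 and 0.022 FPKM in cKO.

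Of 18 BMP and TGF-beta target genes 5 rose, 3 fell and 10 did not pass (9 higher and 4 lower when adjusted over the list alone). The median was 0.21 (0.14 without control 2 and 0.10 with no filter), the mean -0.07 and the camera adjusted p 0.734. Tgfbi, a secreted matrix protein, fell from 88.7 ± 4.22 to 39.2 ± 9.07 FPKM, Bambi, a decoy receptor, from 4.85 ± 0.340 to 2.26 ± 0.421 FPKM, and Smad7, an inhibitory SMAD, rose from 6.06 ± 0.014 to 9.64 ± 1.35 FPKM. Of 13 Wnt target genes Rnf43 rose, Wif1 fell and 11 did not pass, also when adjusted over the list alone (median 0.01, mean -0.06, camera downward, adjusted p = 0.576). Wif1, a Wnt inhibitor, did not pass without control 2 or 3 or cKO 1 (limma adjusted p 0.0507 to 0.0981), and Rnf43, a ubiquitin ligase for Wnt receptors, without control 2 or 3 or any cKO library (0.0719 to 0.122).

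Cell cycle genes were higher. Of 41 tested, 12 rose, 0 fell and 29 did not pass (21 higher when adjusted over the list alone), with a median of 0.20 (camera adjusted p = 4.71e-05). The list had adjusted p = 0.579 with an estimated correlation and 0.0305 by fry, and its median was 0.15 with median-of-ratios scaling and 0.13 with quantile normalization. Rrm2, a subunit of ribonucleotide reductase, rose from 148 ± 9.42 to 259 ± 32.7 FPKM, and Birc5, the mitotic protein survivin, from 62.0 ± 1.51 to 85.0 ± 7.18 FPKM. Inflammatory and matrix-degrading genes were lower, with 6 of 17 falling, 0 rising and 11 not passing (7 lower and 1 higher when adjusted over the list alone). Their median was -0.36 (camera adjusted p = 0.00117), with adjusted p = 0.579 with an estimated correlation and 0.0305 by fry. It was -0.21 without control 2, -0.20 at a mean of 2 FPKM or more and -0.23 without a filter. Lcn2, an iron-binding protein of inflammation, fell from 50.1 ± 11.4 to 9.88 ± 0.841 FPKM and Mmp3, a matrix metalloproteinase, from 49.3 ± 12.6 to 11.9 ± 5.16 FPKM.

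**Figure D3:**
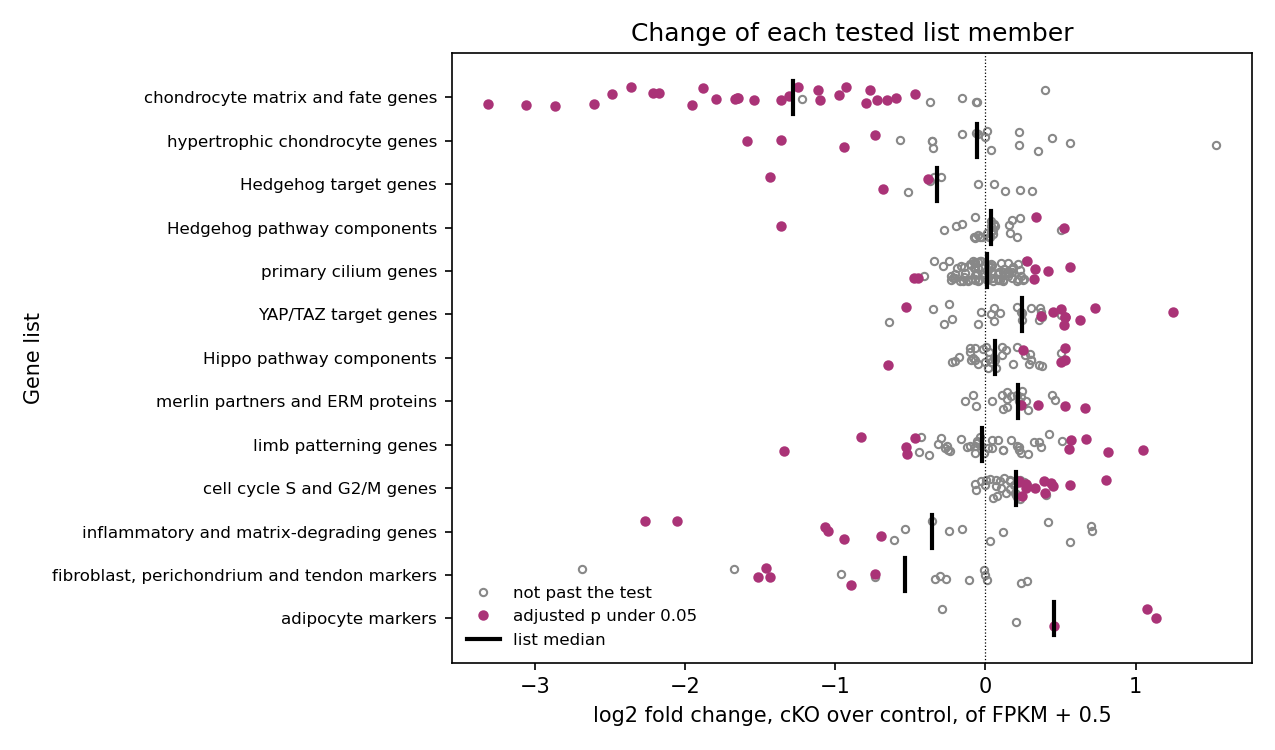
Log2 fold change, cKO over control, of FPKM + 0.5 (horizontal axis) for every tested member of 13 gene lists (vertical axis), with filled points past limma at adjusted p under 0.05, open points not past it and bars at list medians. The chondrocyte list has a median of -1.28 and 28 of 34 members past the test, all lower, while primary cilium genes centre at 0.01.

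The 8 largest rises past the test included 5 mitochondrial transfer RNA genes, led by mt-Ts2 (log2 change 3.52), mt-Th (3.48) and mt-Tl2 (3.42), which lie side by side between 11546 and 11741 of the mitochondrial genome, followed by mt-Tg (2.21) and mt-Tr (1.53). Krt19, an epithelial keratin, rose from 8.21 ± 2.24 to 29.1 ± 12.9 FPKM (limma adjusted p = 0.00975, 0.0634 without a filter), Gsta1, a glutathione transferase, from 10.2 ± 1.84 to 34.9 ± 10.9 FPKM, and Car3, a carbonic anhydrase, from 2.61 ± 0.618 to 8.12 ± 0.378 FPKM. Among the 8 largest falls, Clec3a and Ucma, both cartilage matrix proteins, fell from 24.2 ± 4.96 to 1.61 ± 0.071 FPKM and from 66.8 ± 12.0 to 6.45 ± 2.14 FPKM. The others are not typical of cartilage. Zg16, a lectin of intestinal mucus, was at 5.37, 5.90 and 13.0 FPKM in control 1 to 3 and Igkc, an antibody light chain, at 3.23, 2.10 and 7.73 FPKM, and both were listed at 0 in all 3 cKO libraries. Sprr2a2 (15.7, 14.8 and 10.4 FPKM) and Sprr2a1 (4.06, 5.05 and 10.4 FPKM) were also listed at 0 in every cKO library, and because these paralogs are nearly identical the split of reads between them is uncertain. Lypd8 was at 6.18, 6.09 and 14.7 FPKM and Plac8 at 7.49, 6.18 and 13.6 FPKM in control 1 to 3, and their highest cKO values were 0.083 and 0.239 FPKM. These transcripts moved with the same groups as the cartilage genes. Taking the large-intestine and Sprr2a genes off the finished list, with no new fit, left 1695 genes past the test. That count does not show whether the source of these transcripts affects other genes.

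Of 4356 term tests 86 passed, 43 among higher and 43 among lower genes (1-sided Fisher exact test, Benjamini-Hochberg). Lower genes held 44 of 162 genes of collagen-containing extracellular matrix (7.50 by chance), 13 of 30 of cartilage development and 7 of 14 of chondrocyte differentiation. Higher genes held 25 of 109 genes of actin cytoskeleton organization (8.30 by chance), 15 of 53 of stress fiber and 7 of 14 of the translation initiation factor 3 complex. The count was 47 without control 1 and 43 without control 2, and 56 with median-of-ratios scaling (19 higher, 37 lower) or 49 with quantile normalization (12 higher, 37 lower). Among 27761 single transcripts, 169 of 158 genes passed limma, 52 higher and 117 lower, and 4039 had an unadjusted p under 0.05. That count was 53, 37 and 58 without control 1, 2 and 3, and 62, 59 and 31 without cKO 1, 2 and 3. The authors' deposited table marks 1881 transcripts, 904 higher and 977 lower. Of these, 879 were tested here and 134 passed, all in the same direction.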

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

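Tests chosen only after the results were seen were the Xist covariate, the floor of 200 bases, limma voom on implied fragments, the count without large-intestine genes and the counts over other splits of the libraries. No named gene and no list test reversed its direction in a setting where it passed or had passed, though the median of the adipocyte list was -0.02 with no filter. The count of 1713 genes was 662 with no filter on low values, 1134 for limma without trend, 540 from the highest transcript per gene, 242 with a 2-fold threshold and 537 to 1324 on leaving out 1 library (678 without control 1, 537 without control 2). It stayed within 1401 to 1812 with pseudocounts of 0.1 or 1, a mean of 2 FPKM, median-of-ratios scaling or quantile normalization. Robust fitting, protein-coding transcripts, the Xist covariate, transcripts of 200 bases or longer and voom gave counts in the same range. Taking the large-intestine and Sprr2a genes out of the count, with no new fit, could only lower it, and left 1695. The authors' call marks 1641 genes, 471 of them among the 1713. The 169 transcripts became 42 with no filter, 19 with the Xist covariate and 31 to 62 on leaving out 1 library (53, 37 and 58 without control 1, 2 and 3, and 62, 59 and 31 without cKO 1, 2 and 3). The 10 lists past camera became 0 with an estimated correlation (camera, 1 list at an unadjusted p under 0.05, 6 by fry) and 7 to 11 on leaving out 1 library. The 86 terms became 44 with no filter, 56 with median-of-ratios scaling, 49 with quantile normalization, 42 without trend and 43 to 76 on leaving out 1 library (47 without control 1, 43 without control 2). No filter tests more genes of low signal, and leaving out a library leaves fewer samples, but what caused the change of a count was not tested for any setting. With the replicate number as a replicate block, 1097 genes and 0 transcripts passed limma (3490 transcripts at an unadjusted p under 0.05), and the YAP and TAZ target list lost its call (camera adjusted p = 0.0975). Deviations of libraries with the same number correlated across genes at -0.016, -0.056 and -0.046, and each correlated better with another number. Correlations this close to 0 give no sign of pairing by number, but they cannot exclude that same-numbered samples were prepared together. Over lists, 499 alternative values kept their side of the threshold, 38 lost it and 4 gained it, and over named genes 2674 kept it, 278 lost it and 44 gained it. The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05, and 1 of the 10, the real split, gave as large a count each time. The real and highest other counts were 1713 and 0 genes (limma, 271 to 503 genes at an unadjusted p under 0.05 in the others), 169 and 11 transcripts, 10 and 8 lists, and 86 and 0 terms (Fisher exact test on genes past limma). DESeq2 was not run because the values are not counts. Among genes named in the text, limma lost with no filter the calls of Gli1, Ccn1, Ankrd1, Amotl2, Col2a1, Hand2, Krt19, Gas1, Disp1, Arrb1, Sclt1, Amot, Slc9a3r1, Rac1, Cd200, Bmp6, Tnfrsf11b, Wif1, Rnf43, Klf6, Btg2, Phgdh, Eno1, Aldoa, Ctsk, Itgb3, Acp5, Acta1, Trp63, Dsp, Krt8, Stmn2, Lum, Tagln, Myl9, mt-Co2 and mt-Nd6 (adjusted p 0.0515 to 0.357). Medians close to 0 changed sign on leaving out 1 library for the Hedgehog component list (control 2 or cKO 1), cilium list (control 1 or 2 or cKO 2), limb patterning list (control 3 or cKO 1 or 2), Wnt list (control 1 or any cKO library) and unfolded protein response list (cKO 3), and the Hippo component median was 0.10 without control 1 and 0.04 without control 2. Hhip, Hoxd13, Hoxa13 and Alx4 lay under the filter, and with no filter they did not pass limma (adjusted p = 0.0621 for Hhip and 0.369 to 0.511 for the others). Whether more depth would change this was not tested.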

Other observations

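All tests in this part on large-intestine transcripts, mitochondrial transfer RNAs and the cartilage fall were chosen only after the results were seen, whereas the gene lists described first were fixed before.

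Most single genes of the stress, interferon and mitochondrial lists did not pass limma. Of 17 immediate early genes 2 rose, Klf6 and Btg2, 0 fell and 15 did not pass. When adjusted over the list alone, 3 were higher. Their list had a median of 0.13 (camera adjusted p = 0.159), and of 0.08 with median-of-ratios scaling. Klf6, a zinc finger factor, went from 34.1 ± 0.502 to 50.04 ± 6.67 FPKM, a call lost without control 2 (limma adjusted p = 0.0509) or a filter (0.0541), and Btg2, an antiproliferative gene, lost its call without any control or cKO 3 (0.0520 to 0.0772). Of 19 unfolded protein response and amino acid stress genes 1 rose, Phgdh, and 18 did not pass (0 by limma when adjusted over the list alone, 2 at an unadjusted p under 0.05; median 0.004, camera downward, adjusted p = 0.684), and Phgdh passed without cKO 3 but not without any other library (0.0755 to 0.145). Of 19 hypoxia and glycolysis genes Eno1 and Aldoa, glycolytic enzymes, rose and 17 did not pass (7 higher and 1 lower when adjusted over the list alone; median 0.14, 0.09 without cKO 3; camera adjusted p = 0.684, fry 0.0147). Eno1 did not pass without control 1 or 2 or cKO 1 or 2 (0.0713 to 0.155), nor Aldoa without those or cKO 3 (0.0666 to 0.162). Of 15 interferon response genes 0 passed limma, 3 at an unadjusted p under 0.05, also 0 when adjusted over the list alone. Their median was -0.16 (camera adjusted p = 0.0257), with adjusted p = 0.665 with an estimated correlation, 0.375 by fry, 0.172 at a mean of 2 FPKM, 0.0810 with quantile normalization, and 0.0890, 0.0717, 0.0983 and 0.0612 without control 1, control 3, cKO 2 and cKO 3. The median was -0.10 without control 3 and -0.09 without cKO 2. Of 13 mitochondrially encoded protein genes mt-Co2 and mt-Nd6 fell and 11 did not pass (5 lower when adjusted over the list alone; median -0.22, camera adjusted p = 7.38e-05). That list had adjusted p = 0.661 with an estimated correlation, 0.0735 by fry and 0.168 with quantile normalization, where its median was -0.07. The mt-Co2 call was lost without any control or cKO 1 or 2 (0.0505 to 0.141), as was that of mt-Nd6 (0.0812 to 0.185).

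Markers of other cell types moved in different directions. All 4 tested osteoclast markers fell, also when adjusted over the list alone (median -0.62), among them Ctsk, the collagen-degrading cathepsin K, from 85.6 ± 10.6 to 50.8 ± 8.67 FPKM, and Itgb3, an integrin subunit, from 2.49 ± 0.392 to 1.21 ± 0.123 FPKM. Ctsk and Itgb3 did not pass without control 2 (limma adjusted p = 0.0559 and 0.0576) or a filter (0.0645 and 0.0607), nor Acp5 without any control or cKO 1 or 2 (0.0953 to 0.151). Of 6 macrophage and leukocyte markers Mrc1, a mannose receptor, rose from 0.934 ± 0.183 to 2.83 ± 0.373 FPKM and 5 did not pass, also when adjusted over the list alone (median -0.29, but -0.51 without control 1, -0.0058 without control 3 and -0.83 without cKO 1; camera adjusted p = 0.684). Of 3 endothelial markers Erg, also a factor of joint cartilage, fell from 15.8 ± 0.911 to 6.62 ± 1.88 FPKM and 2 did not pass (1 higher and 1 lower when adjusted over the list alone; median -0.02). Of 5 skeletal muscle markers Des, the filament protein desmin, and Acta1 rose and 3 did not pass (2 higher when adjusted over the list alone; median 0.27, but 0.11, 0.59, 0.47 and 0.06 without control 1, control 3, cKO 2 and cKO 3 and 8e-04 with no filter; camera adjusted p = 0.219), with Des going from 3.62 ± 0.452 to 7.05 ± 0.491 FPKM and Acta1 lost without control 2 or 3 or cKO 2 or 3 (0.0679 to 0.0981). Of 8 smooth muscle and pericyte markers Tagln and Myl9 rose and 6 did not pass (4 higher and 1 lower when adjusted over the list alone; median 0.19, 0.29 and 0.32 without control 1 and 3; camera adjusted p = 0.576). Tagln, an actin-binding protein, went from 78.2 ± 6.17 to 122 ± 16.0 FPKM but did not pass without a filter (0.0555), and Myl9 did not pass without any control or cKO 1 or 3 (0.0625 to 0.133). Of 8 epidermal markers Trp63 and Dsp rose, Krt8 fell and 5 did not pass (3 higher and 2 lower when adjusted over the list alone; median 0.35, 0.15 with no filter and 0.67 at a mean of 2 FPKM; camera adjusted p = 0.734). None of these 3 calls held without control 1, 2 or 3 or cKO 1 (0.0515 to 0.0979), and those of Trp63 and Krt8 were also lost without cKO 2 (0.0569 and 0.0659). Of 3 glial and neuronal markers Stmn2 rose, Cdh19 fell and 1 did not pass (2 higher and 1 lower when adjusted over the list alone; median 0.43), with Cdh19, a Schwann cell precursor cadherin, going from 2.01 ± 0.300 to 0.526 ± 0.036 FPKM and Stmn2 lost without control 1 or 2 or any cKO library (0.0733 to 0.123). None of the 5 sex-linked genes passed limma (0, with 0 at an unadjusted p under 0.05; median -0.18, and -1.10 to 0.80 on leaving out 1 library; camera adjusted p = 0.684), and 0 of the erythroid markers reached the filter, so limma tested none. The osteoclast, endothelial, glial and erythroid lists had too few tested members for camera, and with no filter and the preset correlation the osteoclast list (median -0.46, camera adjusted p = 4.71e-05) and the erythroid list (-0.33, 0.0120) passed. The endothelial list (0.03, 0.806) and the glial list (-0.05, 0.806) did not. Chosen after their values were seen, Enpp2, the enzyme autotaxin, fell from 48.2 ± 1.55 to 7.46 ± 0.332 FPKM, Frzb, a Wnt antagonist of cartilage, from 9.82 ± 0.241 to 1.69 ± 0.110 FPKM, and Krt7, an epithelial keratin, rose from 4.38 ± 0.690 to 11.2 ± 1.64 FPKM.

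Many large-intestine transcripts were lower in cKO than in control, but not all of them. Of 58 genes abundant in large intestine, a list written after Zg16, Lypd8 and Plac8 had been seen, 49 are in the table and 18 reached the filter, of which 15 passed limma, all lower in cKO, while Krt8 and Epcam are also in the epidermal list. The 15 include Zg16, Lypd8, Plac8 and Igkc, which had already been seen among the largest falls. Members at or near 0 in cKO could reach the filter only through the controls. The count of 15 and its direction were therefore partly fixed beforehand and decide nothing about the source. Other members were present in every cKO library, with Cdh17, which did not pass, at 2.04, 2.03 and 2.15 FPKM in control 1 to 3 and at 3.37, 2.43 and 3.22 FPKM in cKO 1 to 3, while the mucosal genes Muc2 and Slc26a3 reached at most 0.244 and 0.058 FPKM in controls. The 31 under the filter were not tested, and of the 34 without a call 85.3% had a higher mean in control, a share that rests on values near 0 and decides nothing. Control 3 was the highest control for 16 of the 18 tested genes and 42 of the 48 above 0 in a control, and RNA of another tissue in the control libraries and expression by the control cells may both give this and cannot be told apart, because a culture that differed would also give 1 library the highest values.

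The 3 adjacent mitochondrial transfer RNA genes mt-Th, mt-Ts2 and mt-Tl2 rose from means of 14.9, 14.2 and 15.6 FPKM to 163, 160 and 162 FPKM. A bias of very short transcripts would raise others alike, but the 262 tested non-mitochondrial transcripts under 200 bases had a median log2 change of -0.12 (SD 0.47). The remaining mitochondrial transfer RNAs were left out of that comparison. They moved both ways, with log2 changes from 2.21 for mt-Tg to -0.97 for mt-Tc, so a bias limited to such RNAs was not tested. More transcription of the whole mitochondrial genome is argued against by a median of -0.218 (SD 0.11) over 13 mitochondrial protein-coding genes. Of 22 mitochondrial transfer RNA genes 9 rose, 5 fell and 8 did not pass. A difference in transcript processing, in fragments kept from so short RNAs or in the assignment of reads within this block may remain, and none of these was tested.

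The fall of the chondrocyte genes was weighed against the makeup of the cultures. The test chosen was whether markers of other cell types rose alike, as a lower share of chondrocytes might make them do. The fibroblast list score changed by -1.215 (SE 0.242, log2) relative to the adipocyte list score. Because a lower share need not raise every other cell type, this difference cannot decide about it. That difference was -0.803 (SE 0.190) with no filter, where the adipocyte list lost its call, and -1.380 to -1.064 on leaving out each library. The fall did not rest on 1 library, since the list median stayed between -1.455 and -1.158 on leaving out each library. A lower share of chondrocytes therefore stays open. An effect of genotype may also give the same values, and it was not tested. The same holds for a culture difference that followed genotype, such as a change in the fibroblast-like cells themselves.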
